A study of Homo sapiens with 6 samples.

How the data were processed

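The series holds 6 RNA-seq libraries from hypoxic MDA-MB-231 cells, 3 from cells given DMSO and 3 from cells given TGP-210-RL, each for 24 h; the design text calls them biological triplicates. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries with random priming, and sequenced in pairs on a NextSeq500. Because the RNA was fragmented total RNA, mature microRNAs were not the object of these libraries. Samples were assigned to groups by their titles and treatment labels.

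The authors deposited 1 table with 1 row per gene and library and a pair of value columns. The values of both, made by the authors before they were deposited, are treated here as a signal that is never negative. The first is TPM, a measure of abundance corrected for transcript length and library size that the authors summed per Ensembl gene, per the file headers. The second is named scaled reads per base in the file headers, and is taken here as a scaled estimate of reads per gene. The submitters' processing notes name Trimmomatic 0.35, FastQC 0.11.4, kallisto 0.42.4, sleuth 0.30.0 and the build hg19, with no role or order. Kallisto assigns reads to transcripts without placing them on the genome and divides reads among similar transcripts, so the values of paralogs and pseudogenes depend on that division. The transcript set and the use of strand were not given in the sources used here, so overlapping and antisense genes carry the same uncertainty.

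The TPM of a library summed to between 808465 and 967538 over the listed genes rather than to the same total, so the deposited values either omit transcripts or had been rescaled between libraries. Low scaled reads (under 15) lay within 0.05 of a whole number for 33.4% to 36.1% of values when multiplied by 1 factor per library (0.95 to 1.09), where chance gives 10%. The values therefore carry a scaling factor per library, and whole reads could not be restored from them. Undoing these factors gives totals of 7680488 to 8554880 per library. Neither column holds counts, so no count model was used, and the precision of each value was taken from the spread between libraries. No gene had the same value above 0 in any pair of libraries, and every pair correlated at 0.978 to 0.986, so no library was a copy of another. Each library counted as 1 replicate because the design text calls them biological triplicates.

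Gene IDs were matched to symbols with a table of gene names and with GENCODE 29, which gave a symbol to 18463 of 19053 IDs. GENCODE 29 describes another genome build than the one the submitters name, so no coordinates are given and the annotation was used only for names, gene types, coding lengths and 3' UTR sequence.

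The test fixed before the data were examined was a count test, with limma on log2(value + 1) as its replacement for a table without counts. The replacement was used. TPM values were transformed as log2(TPM + 1), genes with a mean of at least 1 TPM over the 6 libraries were kept (16937 genes: 14179 protein-coding, 1924 pseudogenes and 522 absent from GENCODE 29), and limma 3.58.1 in R 4.3.3 fitted the 2 groups with empirical Bayes moderation and a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(TPM + 1) scale and understates the change of genes near 1 TPM. Errors are SD for TPM and SE for log2 fold changes.

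The test was checked on simulated data: in 20 simulations over the 16937 genes, 200 genes were changed by 1.5-fold, 2-fold or 3-fold. The test recovered 38.1%, 69.2% and 85.5% of these over all abundances and 60.7%, 95.6% and 99.9% above 10 TPM, with a mean share of false calls of 7.63%. Values were drawn independently for each gene from its mean and fitted variance, so trends within libraries and correlation between genes were left out.

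The genes named in the text follow a rule fixed before the data were examined. Since under 10 genes passed, these are the 10 genes with the smallest unadjusted p; genes tied to the compound or to hypoxia (MIR210HG, MIR210, GPD1L, HIF1A, EFNA3, ISCU, CA9, VEGFA and BNIP3); and up to 4 members with the smallest p from each list described. MIR210HG and MIR210 were not analysed here. A further fixed gene and 1 of the 28 tested lists are not reported here. Other genes are said to be chosen after their values were seen.

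A set of 30 gene lists and 5 marker lists was also fixed before the data were examined, from general knowledge of pathways and not from these samples. Of these lists, 2 (abundant small noncoding RNAs and nuclear long noncoding RNAs) had no member in the tested genes and were not analysed here. The other 28 were tested with camera, which compares a list's genes with all other genes, at a preset correlation between genes of 0.01, and again with a correlation estimated from the libraries. Fry, which tests a list's genes without comparing them with other genes, was run for change on balance one way and for change in either direction. Each test was adjusted over the 28 lists, or over the 5 marker lists. The p of single members was also adjusted over their list alone, which takes no account of the number of lists examined. The estimated correlations were far above the preset value in most lists, as in ribosomal proteins (0.89).

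The alternatives were other scalings of the TPM (median of ratios, upper quartile, equal totals with and without mitochondrial and small noncoding RNAs), pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 TPM, protein-coding genes only, other thresholds, each library left out in turn, and the replicate number as a block. Scaled reads per base, quantile and cyclic loess normalization, array weights, a per-library correction for TPM and coding length in protein-coding genes, and the count at an unadjusted p under 0.05 were added after the data were seen. All 10 splits of the 6 libraries into 3 and 3 were refitted.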

Results

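The series asks how selective a small molecule that degrades a hypoxia-associated noncoding RNA is across the transcriptome. MDA-MB-231 cells, an established triple-negative breast cancer line, were kept under 1% oxygen and given either the solvent DMSO (vehicle, 3 libraries) or TGP-210-RL (3 libraries) for 24 h. TGP-210-RL is a compound that binds the hairpin precursor of the microRNA miR-210 and leads to its degradation. The dose was not given in the sources used here. Abundance was given as TPM (an abundance corrected for transcript length and library size) for 19053 genes in each of the 6 libraries, which were made from total RNA depleted of ribosomal RNA. The authors' scaled reads per base summed to between 7017349 and 8542067 per library, which is not known to be the number of sequenced reads. The series has no normoxic group, so values refer to hypoxic cells only.

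The libraries resembled each other closely, with Pearson correlations of log2(TPM + 1) across the tested genes between 0.978 and 0.986 (genes are not independent replicates). Vehicle replicate 1 stood apart. Its TPM summed to 808465, against 892320 to 967538 in the other 5 libraries, and its most abundant genes were low relative to the other vehicle libraries. Among the 20% of genes with the highest TPM its median deviation was -0.22 on the log2 scale, while that of vehicle replicate 3 was 0.22. The first principal component, with 33.5% of the variance, placed vehicle replicates 1, 2 and 3 at -31.8, -12.4 and 19.4. TGP-210-RL replicates 1, 2 and 3 lay at 0.43, 4.70 and 19.7. Vehicle replicates 1 and 2 thus lay below every TGP-210-RL library, but vehicle replicate 3 lay among them, so the main axis of variation did not separate the groups.

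**Figure D1:**
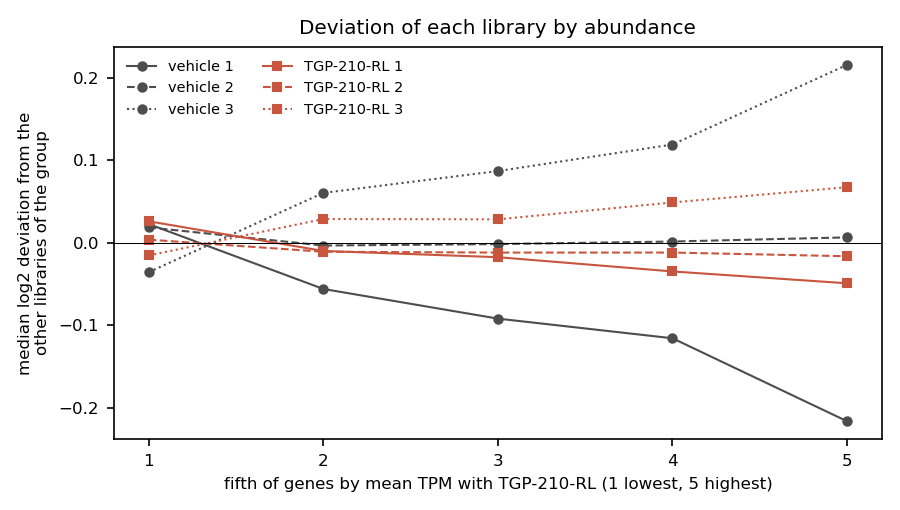
Median log2 deviation of each library from the other libraries of its own group, in 5 equal bins of 12244 genes ordered by mean TPM with TGP-210-RL. Circles are vehicle libraries and squares TGP-210-RL libraries; in the top bin vehicle replicate 1 lies at -0.22 and vehicle replicate 3 at 0.22, while the TGP-210-RL libraries lie between -0.049 and 0.068.

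Across the transcriptome of hypoxic cells, no gene passed the test between TGP-210-RL and vehicle. With limma, 0 of 16937 genes reached a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.118. At an unadjusted p under 0.05 there were 842 genes, 360 higher and 482 lower with TGP-210-RL, where 846.85 are expected by chance. With every library scaled to the same total the split was 155 higher and 816 lower. The 3 TGP-210-RL values lay all above or all below the 3 vehicle values in 1895 genes (11.2%), where chance gives 10%. The median log2 fold change over all tested genes was 0.026, and the median standard error of a log2 fold change was 0.14. For 94.1% of the genes the 95% interval of the fold change lay within 2-fold in either direction, and for 71.5% within 1.5-fold. These folds are on the log2(TPM + 1) scale, which understates changes in genes near 1 TPM. For such genes the shares do not bound the change in TPM. In simulated data with 3 values per group, the test recovered 95.6% of 2-fold changes and 60.7% of 1.5-fold changes in genes above 10 TPM. Over all abundances the shares were 69.2% and 38.1%. The simulated data held 200 changed genes, independent noise and no trend between libraries, so these shares can overstate recovery in the real libraries. *RPL36AP30*, with a log2 fold change of -1.49, did not pass.

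**Figure D2:**
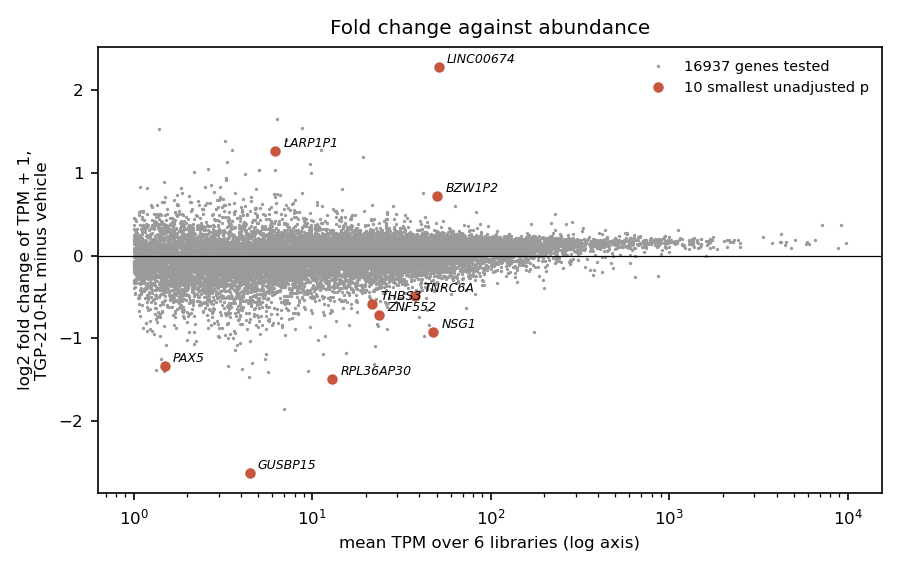
Log2 fold change of TPM + 1 (TGP-210-RL minus vehicle) against mean TPM over the 6 libraries on a log axis, 1 point per gene, for 16937 genes. The 10 genes with the smallest unadjusted p are labelled; none passed the adjusted threshold, and the smallest adjusted p is that of *RPL36AP30* at 0.118.

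The 10 genes with the smallest unadjusted p are described here although none of them passed. Among protein-coding genes, *ZNF552* (ENSG00000178935), a zinc finger gene, measured 29.9 ± 2.89 TPM with vehicle and 17.8 ± 0.920 TPM with TGP-210-RL (SD, n = 3 each), a log2 fold change of -0.71 ± 0.11 (SE) with adjusted p = 0.534. *THBS3* (ENSG00000169231), which encodes an extracellular thrombospondin, measured 26.4 ± 1.69 TPM with vehicle and 17.2 ± 1.04 TPM with TGP-210-RL (adjusted p = 0.623). *NSG1* (ENSG00000168824), a neuronal vesicle trafficking gene, measured 62.6 ± 10.2 TPM with vehicle and 32.7 ± 6.87 TPM with TGP-210-RL (adjusted p = 0.623). *TNRC6A* (ENSG00000090905), which encodes a scaffold of the microRNA silencing complex, measured 44.1 ± 3.60 TPM with vehicle and 31.2 ± 0.496 TPM with TGP-210-RL (adjusted p = 0.667). *PAX5* (ENSG00000196092), a B-cell transcription factor, was close to the lower limit of testing at 2.57 ± 0.131 TPM with vehicle and 0.418 ± 0.105 TPM with TGP-210-RL (adjusted p = 0.348). All 5 had lower values in the 3 TGP-210-RL libraries than in the 3 vehicle libraries.

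The other 5 of these 10 genes are annotated as pseudogenes in GENCODE 29, whose reads can be divided between near-identical copies, so their values are uncertain. *RPL36AP30* (ENSG00000224629) measured 19.5 ± 1.87 TPM with vehicle and 6.35 ± 1.33 TPM with TGP-210-RL (SD, n = 3 each), a log2 fold change of -1.49 ± 0.16 (SE) and the smallest adjusted p, 0.118. The parent genes, chosen after their values were seen, had log2 fold changes of 0.12 ± 0.10 for *RPL36A*, 0.26 ± 0.11 for *BZW1*, 0.093 ± 0.091 for *LARP1* and -0.0057 ± 0.10 for *GUSB*, and none passed; the groups did not overlap for *BZW1*. *LINC00674* (ENSG00000237854) had the largest positive log2 fold change of the 10, 2.27 ± 0.38, with 12.0, 33.8 and 10.1 TPM in the vehicle libraries and 59.2, 90.5 and 102 TPM in the TGP-210-RL libraries. *LARP1P1* (ENSG00000217159) had a log2 fold change of 1.26 ± 0.20 and *BZW1P2* (ENSG00000198406) of 0.72 ± 0.12. *GUSBP15* (ENSG00000196302) was listed at 1.10e-06, 1.73 and 0.00256 TPM with TGP-210-RL and at 4.04, 12.7 and 8.34 TPM with vehicle. Adjusted p was 0.592 for the last 4. *RPL36AP30* passed when only genes with a mean of at least 5 TPM were tested (adjusted p = 0.037), and *LINC00674* passed without vehicle replicate 2 (adjusted p = 0.0115). With array weights, whose estimation did not converge, 7 of the 10 passed: *RPL36AP30*, *PAX5*, *ZNF552*, *LARP1P1*, *BZW1P2*, *GUSBP15* and *THBS3*.

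**Figure D3:**
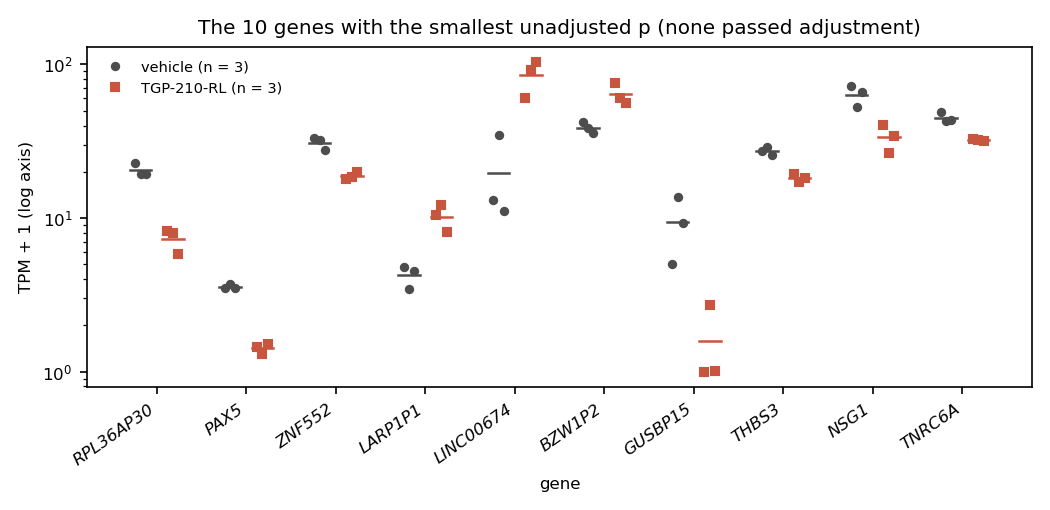
TPM + 1 on a log axis in each library for the 10 genes with the smallest unadjusted p; circles are the 3 vehicle libraries, squares the 3 TGP-210-RL libraries and bars the group means. The groups do not overlap in any of the 10, and no gene passed the adjusted threshold.

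The degraded RNA itself could not be followed here. *MIR210* and its host transcript *MIR210HG* were not analysed here. The known targets of miR-210, which the microRNA holds down in hypoxic cells, showed no detectable shift. *GPD1L*, a target whose product feeds back on HIF-1, measured 9.03 ± 1.18 TPM with vehicle and 9.98 ± 2.05 TPM with TGP-210-RL (SD, n = 3 each), a log2 fold change of 0.12 with a 95% interval from -0.27 to 0.51. *ISCU*, an iron-sulfur cluster scaffold, had a log2 fold change of 0.13 (-0.12 to 0.39). *EFNA3*, an ephrin ligand, had 0.12 (-0.31 to 0.55). The values of *GPD1L* and *EFNA3* were negative without TGP-210-RL replicate 3 and with array weights. *HIF1A*, the oxygen-regulated transcription factor subunit, measured 487 ± 54.3 TPM with vehicle and 459 ± 49.7 TPM with TGP-210-RL (log2 fold change -0.085 ± 0.12, SE); its value was positive without vehicle replicate 1. Adjusted p lay between 0.803 and 0.876 for these 4 genes.

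Of 43 miR-210 targets tested, 35 had a positive and 8 a negative log2 fold change, with a median of 0.083. None reached an adjusted p under 0.05 over all genes or adjusted over the list alone. The 4 members with the smallest p went both ways, with log2 fold changes of -0.21 for the phosphatase gene *PTPN2*, 0.18 for *SERTAD2*, 0.16 for the cohesin loader gene *NIPBL* and -0.21 for *MNT*, a MYC antagonist. The list did not differ from the other genes (camera adjusted p = 0.0761 at the preset correlation; adjusted p = 0.709 with an estimated correlation), and it passed at the preset correlation in 3 alternatives: without vehicle replicate 3 (median 0.13), without a filter and with scaled reads per base. Without vehicle replicate 1 its median was 0.032 (adjusted p = 0.496). Its median was -0.010 when libraries were scaled to equal totals, so the direction depended on the scaling. Random gene sets of matched abundance had a median of 0.070 on the deposited TPM, and the list lay at percentile 71.6 among them.

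**Figure D4:**
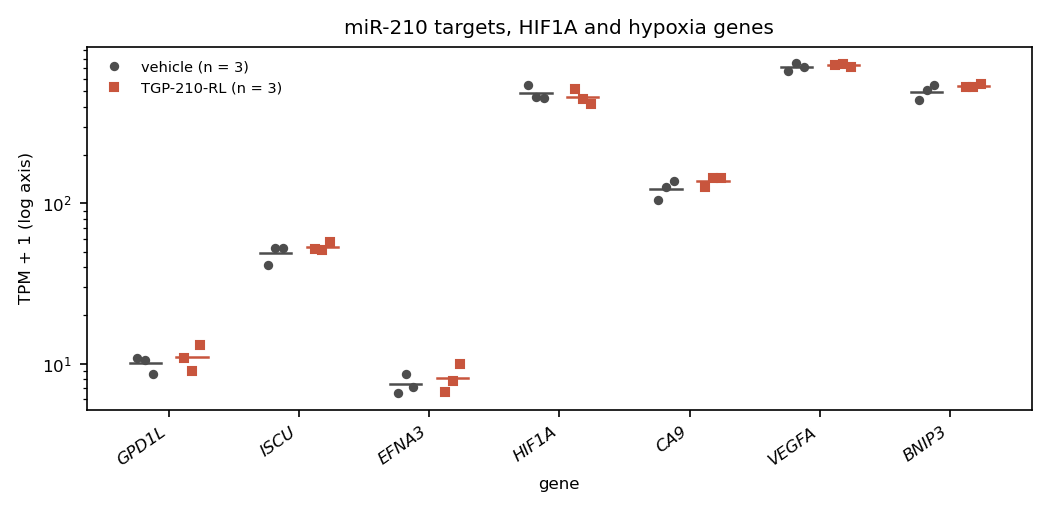
TPM + 1 on a log axis in each library for 3 miR-210 targets, *HIF1A* and 3 hypoxia-induced genes; circles are the 3 vehicle libraries, squares the 3 TGP-210-RL libraries and bars the group means. The groups overlap for all 7 genes, and the log2 fold changes run from -0.085 for *HIF1A* to 0.17 for *CA9*.

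Hypoxia-induced genes were abundant with both treatments. *VEGFA*, the angiogenic growth factor gene, measured 709 ± 35.8 TPM with vehicle and 729.7 ± 14.9 TPM with TGP-210-RL (SD, n = 3 each), *BNIP3*, a mitophagy receptor gene, 498 ± 52.0 TPM with vehicle and 538 ± 13.3 TPM with TGP-210-RL, and *CA9*, carbonic anhydrase 9, 123 ± 16.7 TPM with vehicle and 137 ± 9.61 TPM with TGP-210-RL. Their log2 fold changes were *VEGFA* (0.042 ± 0.093), *BNIP3* (0.12 ± 0.10) and *CA9* (0.17 ± 0.11) (SE), with adjusted p of 0.914, 0.806 and 0.801. The value of *VEGFA* was negative in 6 alternatives, among them equal library totals, and that of *BNIP3* in 3, among them quantile normalization. Of 73 tested HIF target genes, 65 had a positive log2 fold change and 0 passed singly; the median was 0.14. The list ranked above the other genes at the preset correlation (camera adjusted p = 1.08e-06) but not with an estimated correlation (adjusted p = 0.709). Its members with the smallest p were *MXI1* (0.30 ± 0.084), *STC1* (0.27 ± 0.10), *LOX* (0.26 ± 0.10) and *ALDOC* (0.29 ± 0.11). *MXI1* encodes a MYC antagonist, *STC1* a secreted stanniocalcin, *LOX* a collagen crosslinking enzyme and *ALDOC* an aldolase. The glycolysis list had a positive log2 fold change in 21 of 24 members (median 0.15, led by *ALDOC* and *HK2*, hexokinase 2, at 0.21), with camera adjusted p = 6.71e-04 and adjusted p = 0.709 with an estimated correlation. HIF pathway regulators had 20 of 23 positive (median 0.12, led by the cullin gene *CUL2* at 0.34), with camera adjusted p = 0.00641 and adjusted p = 0.709 with an estimated correlation; this call ended without vehicle replicate 1. In vehicle replicate 1 the median HIF target stood at 131 TPM, against 146 to 151 in the other 5 libraries, and the median glycolysis gene at 383 against 415 to 478. Without vehicle replicate 1 the medians of HIF targets and glycolysis were 0.058 and 0.056, and with cyclic loess normalization 0.026 and 0.0014. None of these 3 lists passed with quantile or cyclic loess normalization.

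Stress-response lists gave small positive medians. Genes of the unfolded protein response had a positive log2 fold change in 26 of 27 members, with a median of 0.17 (camera adjusted p = 1.39e-06; adjusted p = 0.709 with an estimated correlation). They were led by the ER-associated degradation genes *SYVN1* (0.27 ± 0.082, SE) and *SEL1L* (0.30 ± 0.13) and the chaperone gene *HSPA5* (0.27 ± 0.12). Genes of the ATF4 and amino acid response had 33 of 36 positive (median 0.12; camera adjusted p = 1.53e-04; adjusted p = 0.709 with an estimated correlation), led by *WARS1* (0.21), a tRNA synthetase gene, and *MTHFD2* (0.31), a mitochondrial folate enzyme gene. Immediate early genes had 24 of 27 positive (median 0.15; camera adjusted p = 2.58e-04; adjusted p = 0.709 with an estimated correlation). Their members went both ways, with *NR4A1*, a nuclear receptor gene, at 0.49 ± 0.15 and *IER3* at -1.25 ± 0.41. *IER3* was close to the lower limit of testing, at 2.40 ± 1.65 TPM with vehicle and 0.456 ± 0.789 TPM with TGP-210-RL (SD, n = 3 each). These 3 lists passed at the preset correlation without each library in turn and with quantile and cyclic loess normalization. Over the left-out libraries the medians ran from 0.107 to 0.219, from 0.0752 to 0.19 and from 0.0745 to 0.242, lowest without vehicle replicate 1 and highest without vehicle replicate 3. With equal library totals they were 0.080, 0.038 and 0.061. None of their members passed singly, over all genes or adjusted over the list alone.

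Heat shock genes (18 of 21 positive, median 0.091), NRF2 targets (25 of 30, 0.12) and apoptosis genes (29 of 36, 0.092) passed narrowly at the preset correlation (camera adjusted p = 0.0280, 0.0448 and 0.0324; adjusted p = 0.709 with an estimated correlation for each). These calls depended on single libraries: leaving out 1 library ended the heat shock call in 4 of 6 cases, the NRF2 call in 5 and the apoptosis call in 3. Without vehicle replicate 1 the 3 medians were 0.035, 0.048 and 0.0068, and with equal library totals -0.0031, 0.024 and 0.0037. Random gene sets of matched abundance had medians of 0.101, 0.081 and 0.057, the first of them above the heat shock median. Within the NRF2 list, *ABCC2*, an efflux transporter gene, went against the median, with 5.91 ± 0.828 TPM with vehicle and 2.74 ± 0.506 TPM with TGP-210-RL (SD, n = 3 each) and adjusted p = 0.0248 adjusted over the list alone, against 0.667 over all genes; it passed over all genes with array weights only. The p53 targets (median 0.074, led by the polymerase gene *POLH* at 0.35 and *RPS27L* at 0.25) and the DNA damage and repair genes (median 0.076, led by the Fanconi anemia gene *FANCA* at -0.34) did not pass (camera adjusted p = 0.0704 and 0.871). Both medians were negative with equal library totals, and the p53 list passed at the preset correlation without vehicle replicate 2.

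No interferon or inflammatory response was detectable. Of 49 interferon-stimulated genes, 32 were positive and 17 negative (median 0.053, negative with equal library totals). *IFI27* measured 15.8 ± 5.06 TPM with vehicle and 9.26 ± 2.29 TPM with TGP-210-RL (SD, n = 3 each), and *IFITM3* had a log2 fold change of 0.23. The NF-kB and inflammatory genes split evenly, 15 positive and 15 negative, with *IER3* at -1.25 and the cyclooxygenase gene *PTGS2* at 0.41. The value of *IER3* was close to the lower limit of testing. The median of this list was 0.0023, negative in 7 of 8 other scalings, and camera gave the opposite direction. Camera adjusted p was 0.546 and 0.546 for these 2 lists, and no member passed singly.

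The 13 mitochondrially encoded mRNAs all had a positive log2 fold change, from 0.17 to 0.34 with a median of 0.24. *MT-ND3*, *MT-ND4L*, *MT-ND6* and *MT-ND5*, all subunits of respiratory complex I, had 0.34 ± 0.10, 0.31 ± 0.11, 0.31 ± 0.11 and 0.24 ± 0.10 (SE). None passed singly over all genes, and the smallest p adjusted over the list alone was 0.0916. The list passed at the preset correlation (camera adjusted p = 1.59e-07) and not with an estimated correlation (adjusted p = 0.709), and its median was 0.18 without vehicle replicate 1 and 0.080 with cyclic loess normalization. These mRNAs made up 1.42% ± 0.023 of the TPM with vehicle and 1.57% ± 0.042 with TGP-210-RL (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Nuclear-encoded respiratory chain genes had 47 of 49 positive (median 0.14; camera adjusted p = 1.06e-06; adjusted p = 0.709 with an estimated correlation), led by *NDUFA9* (0.31); without vehicle replicate 1 their median was 0.0455 (adjusted p = 0.0499), and the call ended after correction for TPM and coding length. Cytosolic ribosomal protein genes had 76 of 78 positive (median 0.16; camera adjusted p = 9.85e-09; adjusted p = 0.709 with an estimated correlation), led by *RPL10* (0.29) and *RPL22* (0.30). Their median level was 748 TPM in vehicle replicate 1, against 914 to 1022 in the other 5 libraries, and their median fold change was 0.040 without vehicle replicate 1 and -0.00061 after correction for TPM and coding length. The ribosomal call ended after that correction and with quantile and cyclic loess normalization. Ribosome biogenesis and MYC targets (median 0.072, negative with equal library totals; *MYC* 0.19, *ODC1* 0.23) did not pass (camera adjusted p = 0.128), except without vehicle replicate 3.

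Among proliferation genes, the G2/M and mitosis list had a positive log2 fold change in 42 of 49 members with a median of 0.12 (camera adjusted p = 3.11e-06; adjusted p = 0.709 with an estimated correlation). The mitotic genes *BORA* (0.36 ± 0.13, SE), *CEP55* (0.22 ± 0.090) and *CDK1* (0.19 ± 0.086) had the smallest p. Its call held without each library in turn and with quantile and cyclic loess normalization, while its median was 0.065 without vehicle replicate 1 and 0.030 with equal library totals. S phase and E2F targets split 22 to 15 (median 0.041, negative with equal library totals, with cyclic loess normalization, without vehicle replicate 1 and without TGP-210-RL replicate 3), with the polymerase gene *POLE* at -0.29 and *DTL* at 0.27, and passed only without vehicle replicate 3 among the left-out libraries (camera adjusted p = 0.526 with all 6). Replication-dependent histone genes did not pass (median 0.079, negative in 5 of 8 other scalings; camera adjusted p = 0.188), but without vehicle replicate 1 they passed in the lower direction (median -0.067) and without vehicle replicate 3 in the higher (0.20). Their median level was 171 TPM in vehicle replicate 1 and 238 TPM in vehicle replicate 3. Both histone calls used the preset correlation, while the correlation estimated for this list was 0.863 (camera adjusted p = 0.818 with it and all 6 libraries).

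The genes of microRNA biogenesis and function did not move in one direction, with 9 positive and 10 negative log2 fold changes (median -0.0082; camera adjusted p = 0.557). This list alone passed the test for changes in either direction (fry adjusted p = 0.0333). Its member with the smallest p was *TNRC6A*, at 31.7, 31.05 and 30.7 TPM with TGP-210-RL and 48.2, 41.6 and 42.5 TPM with vehicle, which was lower with adjusted p = 0.00859 adjusted over the list alone and 0.667 over all genes. The 3 next members were *PRKRA* (0.24), a partner of Dicer, and the nuclease genes *DICER1* (-0.12) and *DROSHA* (0.15). Only *TNRC6A* passed adjusted over the list alone. Fry for either direction was run only with all libraries on the deposited TPM, and not without *TNRC6A*.

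Among the other lists, *MVD*, an enzyme gene of the mevalonate pathway, measured 36.8 ± 3.43 TPM with vehicle and 25.6 ± 2.25 TPM with TGP-210-RL (SD, n = 3 each), and was the only sterol and fatty acid synthesis gene to pass adjusted over the list alone (adjusted p = 0.0359, against 0.704 over all genes, where it passed with array weights only). The other leading sterol genes had the opposite sign, with 0.21 for the desaturase gene *SCD*, 0.21 for *CYP51A1* and 0.20 for *INSIG1*, and the list did not pass (median 0.060, negative with equal library totals and with cyclic loess normalization; camera adjusted p = 0.223), except without vehicle replicate 3 (median 0.11, adjusted p = 0.0418). Lysosome and autophagy genes (median 0.16, led by the protease gene *CTSA* at 0.17), extracellular matrix and EMT genes (0.14, with the collagen gene *COL7A1* at -0.43 and the integrin gene *ITGA2* at 0.20) and YAP and TEAD targets (0.10, with *FOXF2* at 0.43 and *CCN2* at 0.21) passed at the preset correlation (camera adjusted p = 0.00136, 0.0157 and 0.00641; adjusted p = 0.709 with an estimated correlation for each). All 3 calls ended without vehicle replicate 1, and the last 2 also without TGP-210-RL replicate 3 (adjusted p = 0.0936 and 0.0648). Without vehicle replicate 1 the 3 medians were 0.062, 0.059 and 0.044, and with equal library totals 0.067, 0.049 and 0.0075. The 9 AHR targets had a median of 0.12 and did not pass (camera adjusted p = 0.546).

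**Figure D5:**
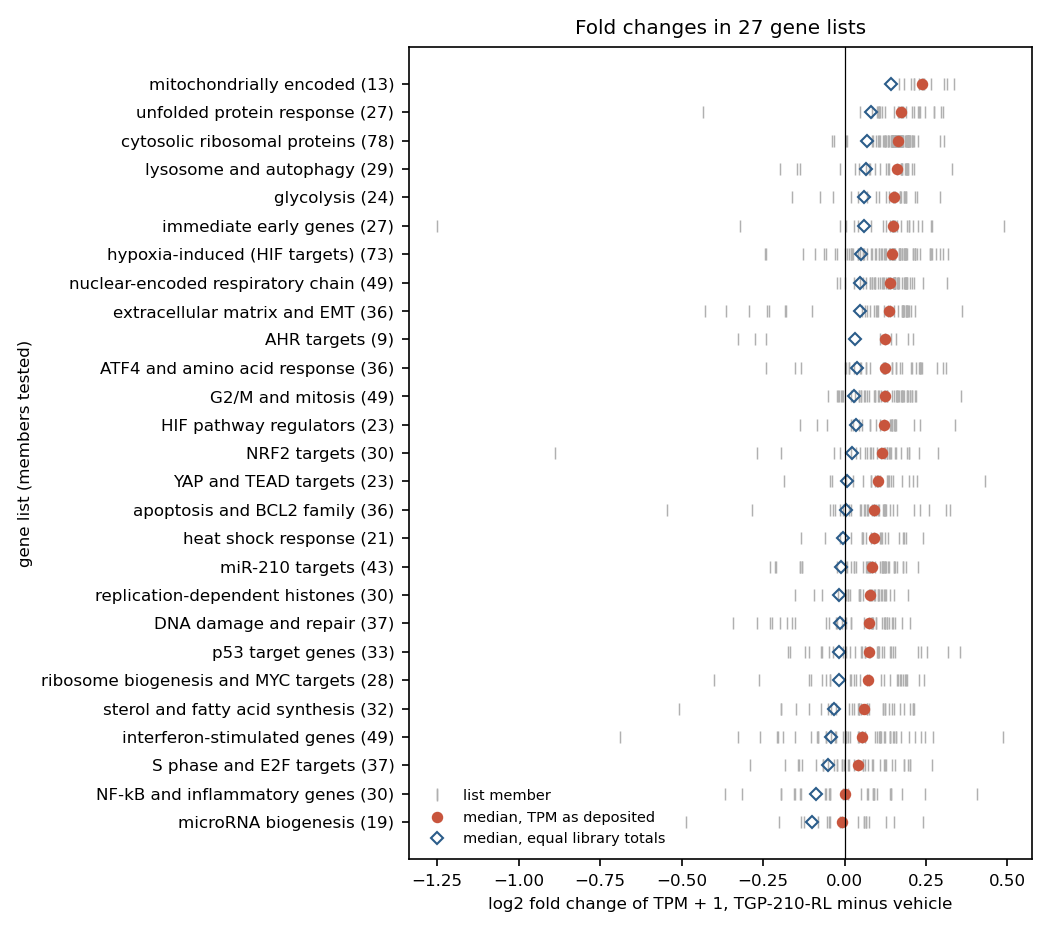
Log2 fold change of TPM + 1 (TGP-210-RL minus vehicle) for the members of 27 gene lists, with the number of members tested in brackets; ticks are single genes, filled circles the list medians on the deposited TPM scale and open diamonds the medians with libraries scaled to equal totals. The filled medians run from -0.0082 for microRNA biogenesis to 0.24 for mitochondrially encoded mRNAs.

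Markers of the line itself and of other cell types were compared in the same way. The 12 MDA-MB-231 markers, such as *CAV1* (0.21) and the AP-1 gene *FOSL1* (0.17), had a median of 0.18 (camera adjusted p = 0.00358 over 5 marker lists; adjusted p = 0.553 with an estimated correlation), and their median level was 259.8 TPM in vehicle replicate 1 against 298 to 347 in the other 5 libraries. This median was 0.082 without vehicle replicate 1 and 0.061 after correction for TPM and coding length. The 8 tested fibroblast markers had a median of -0.20 (camera adjusted p = 0.0218; adjusted p = 0.267 with an estimated correlation; fry adjusted p = 0.0453), negative in every alternative (-0.27 to -0.10), with *COL1A2* at 4.10 ± 0.447 TPM with vehicle and 2.96 ± 0.307 TPM with TGP-210-RL and *COL1A1* at 19.3 ± 1.24 TPM with vehicle and 16.3 ± 2.75 TPM with TGP-210-RL (SD, n = 3 each). The value of -0.10 came with a mean of at least 5 TPM, and all alternatives reuse the same libraries. The median level of these markers overlapped between the groups, at 5.01 to 6.43 TPM with vehicle and 5.41 to 6.25 TPM with TGP-210-RL. Luminal epithelial markers (median 0.13, *EPCAM* 0.21), leukocyte markers (-0.056, *CD68* 0.23) and endothelial markers (-0.041, *TIE1* -0.42) did not pass (camera adjusted p = 0.373, 0.694 and 0.373), and the luminal median was 0.030 without vehicle replicate 1, while the last 2 medians were positive with quantile normalization.

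With 3 libraries per group, the test missed many of the 1.5-fold changes in simulated data, and also part of the 2-fold changes over all abundances. The medians of all 28 tested lists were lower without vehicle replicate 1 than with all libraries, and those of 27 were higher without vehicle replicate 3. All 16 list calls at the preset correlation were positive, and none of them held with an estimated correlation (smallest adjusted p = 0.709) or with fry (smallest adjusted p = 0.51).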

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

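The scaled reads per base, quantile normalization, cyclic loess normalization, array weights, the correction for TPM and coding length, and the count at an unadjusted p were chosen after seeing the data. The count of 0 genes passing held in every alternative except 3: a mean of at least 5 TPM (1 gene, *RPL36AP30*, with fewer genes tested), leaving out vehicle replicate 2 (1 gene, *LINC00674*; the range over the left-out libraries was 0 to 1) and array weights (20 genes, among them 7 of the 10 genes with the smallest p). The array weights rested on vehicle replicate 2, whose weight was 4.9 against 0.352 to 1.55 in the other 5 libraries, and their estimation did not converge. The count at an unadjusted p under 0.05, 842 with all libraries, was 4360 with array weights and ran from 542 (without vehicle replicate 2) to 3114 (without vehicle replicate 3) over the left-out libraries; in the other alternatives it stayed within 1.5 times, apart from the block. Against 16 called lists, all higher, there were 7 with quantile normalization (all higher), 8 with cyclic loess normalization (7 higher, 1 lower) and 6 after the correction for TPM and coding length (5 higher, 1 lower). That correction used protein-coding genes only, where 13 lists were called without it, all higher. Over all tested genes there were 0 called lists with an estimated correlation, 0 with fry and 1 with fry for change in either direction. Over the left-out libraries the number ran from 10 (without vehicle replicate 1; 9 higher, 1 lower) to 21 (without vehicle replicate 3, all higher). A change of direction was counted as a reversal only where a call was made on either side. The replication-dependent histones, uncalled with all libraries, were called lower with cyclic loess normalization (median -0.0445), after the correction for TPM and coding length (-0.0558) and without vehicle replicate 1, with a range of -0.0665 to 0.196 over the left-out libraries. The cytosolic ribosomal proteins, called higher with all libraries, had a median of -0.000613 after that correction. The cause of these changes was not tested beyond the checks of abundance and length under the other observations. Of 145 named genes, 136 kept their direction in every alternative, and 9 changed it in at least 1 without passing; 11 of 3013 gene values under alternatives passed the threshold.

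With the replicate number as a block, 0 genes passed (smallest adjusted p = 0.0574), 1356 genes had an unadjusted p under 0.05 and 16 lists were called. Deviations from the group means correlated at 0.147, 0.0463 and 0.158 across genes between libraries of the same number, so the numbers were not taken to pair the libraries; every library correlated best with its own number, which is a hint from the data only.

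Not run were edgeR, DESeq2 and voom, count filters and tests of single transcripts, because the table holds normalized values summed per gene. The size factors and upper-quartile scaling listed for a count model were applied to the TPM. Without counts, depth limits low genes in a way that cannot be given as an interval.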

Other observations

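The test of 1 scaling factor per library, the tests of scaling and of abundance for the mitochondrial mRNAs, and the test of pseudogenes were chosen after the results they bear on were seen. The bounds for the test with both trends removed were written after list counts with quantile and cyclic loess normalization had been seen. The lists, the fixed genes and the test of single genes were chosen before the data were examined.

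A set of 9 genes with a mean of at least 10 TPM differed by at least 2-fold, none of them passing, and 7 of these were outside the 10 genes with the smallest p; the genes named next were chosen after their values were seen. Among the 9, the largest difference in a protein-coding gene was in *TMEM105*, at 31.5 ± 6.28 TPM with vehicle and 13.01 ± 6.87 TPM with TGP-210-RL (SD, n = 3 each). *XAB2*, a splicing and DNA repair gene, measured 12.6 ± 7.52 TPM with vehicle and 26.1 ± 6.38 TPM with TGP-210-RL, and *ALYREF*, an mRNA export adaptor gene, 22.7 ± 14.0 TPM with vehicle and 8.46 ± 2.52 TPM with TGP-210-RL. Vehicle replicates of *XAB2* ran from 3.91 to 17.4 TPM and those of *ALYREF* from 9.39 to 37.2 TPM, so the spread within the vehicle group was wide. Adjusted p was 0.73 for *TMEM105* and 0.801 for the other 2.

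The vehicle libraries differed from each other by abundance and by length. Relative to the other vehicle libraries, the top 20% of genes by TPM lay below the bottom 20% in vehicle replicate 1 by a log2 difference of -0.2393 (bootstrap 95% interval -0.259 to -0.219) and above it in vehicle replicate 3 (0.252), so 1 scaling factor per library is argued against as the source. At matched TPM, the deviation of vehicle replicate 1 followed coding length, longer genes being relatively higher there. The partial Spearman correlation was 0.301 across 11286 genes, which are not independent (interval 0.282 to 0.317). The length test was run for vehicle replicate 1 only, against the other vehicle libraries, so vehicle replicate 3 may have contributed to this trend. A candidate explanation is that short and long transcripts were sampled differently between libraries, for example through fragment or RNA size. Whether this arose in the cells or in the preparation stays open, since the labels name no batch.

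The 16 positive list calls at the preset correlation may follow from that trend. With the trends of TPM and coding length removed from each library, 5 of the 16 lists were still called higher. They were the unfolded protein response, ATF4 and amino acid response, G2/M and mitosis, immediate early genes and mitochondrially encoded mRNAs. The correction was run on protein-coding genes only, where 13 lists were called higher without it. The drop from 16 may therefore not be due to the removed trends alone. Among random gene sets matched on abundance alone, 9 of the 16 lay above the 95th percentile, and 9 of the 16 were called without vehicle replicate 1, so abundance alone and vehicle replicate 1 alone are left undecided by bounds of 8 and 12 set beforehand. The heat shock and the YAP and TEAD lists lay below the medians of their matched sets (0.091 against 0.101, and 0.102 against 0.105). Glycolysis, ribosomal proteins, HIF pathway regulators, NRF2 targets and apoptosis lay between that median and the 95th percentile. The correction can also remove part of a treatment effect that follows abundance or length. An effect of the compound on the 5 remaining lists stays among the open explanations.

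The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes at an adjusted p under 0.05 (the highest other 4). Every split gives at least 0, so 10 of 10 reached this count and it decides nothing. The real split also gave 842 genes at an unadjusted p under 0.05 (3 splits gave as many, the highest other 2599) and 16 called lists (3 splits, the highest other 20). The highest values of 2599 and 20 came from the split that sets vehicle replicates 1 and 2 with TGP-210-RL replicate 1, which points to a structure of the samples that does not follow the treatment.

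The mitochondrially encoded mRNAs had positive fold changes, with a median above that of random genes matched on abundance and coding length. Their median was 0.0796 with cyclic loess normalization, and the list did not pass with an estimated correlation. Library scaling cannot change their share of a library's TPM, and the lowest TGP-210-RL share exceeded the highest vehicle share by 0.0992 percentage points. The list's median lay at the percentile of 100 among 10000 random sets matched on abundance, with and without vehicle replicate 1, and again at 100 among sets matched on abundance and coding length (median of matched sets 0.134, against 0.238 in the list). These random genes need not vary together, whereas the 13 mRNAs had an estimated correlation of 0.716. The percentile therefore cannot exclude shared variation between libraries, and full transcript length was not matched. Relative to nuclear-encoded respiratory chain genes, the log2 difference was 2.80 ± 0.121 with vehicle and 2.91 ± 0.0599 with TGP-210-RL (SD, n = 3 each), which overlapped (exact permutation test, two-sided p = 0.3). As a hypothesis, mitochondrial transcripts may be slightly more abundant after TGP-210-RL; differences in culture, extraction or ribosomal RNA depletion that follow the groups were not tested and stay open.

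If miR-210 repression were lost within 24 h, genes with a match to its seed in the 3' UTR might rise as a set. Among 14162 protein-coding genes with an annotated 3' UTR, 528 held a match to the 7-base seed of miR-210-3p. Their log2 fold change differed from that of other genes by 0.000449 (95% interval -0.0149 to 0.0158, adjusted for TPM, UTR length and GC content), at the percentile of 74.6 among 59 control heptamers. A mean shift of 0.05 is thus argued against for these genes at 24 h. The interval treats genes as independent and is too narrow for that reason, though all 59 controls lay between -0.0333 and 0.0164. Single targets with larger responses are not excluded by a set average.

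Reads shared between near-identical copies may account for part of the smallest p. Pseudogenes made up 20.5% of the 200 genes with the smallest p and 11.3% of the other tested genes, an odds ratio of 2 (95% interval 1.37 to 2.92) within 5 bins of TPM. The median SE of a log2 fold change was 0.233 for pseudogenes and 0.13 for protein-coding genes. A change in the expression of the pseudogenes themselves stays open, because the reads were not examined.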
